A study of Zea mays with 72 samples.

How the data were processed

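Gene expression was measured in 72 samples on 36 Agilent 2-colour oligonucleotide arrays, with 3 arrays for each of 3 mutants and 4 stages. Each array carried 1 mutant and 1 fertile sibling sample of the same family, stage and replicate number, labelled with opposite dyes. The series describes the replicates as biological. The labels give 51 plant codes, of which 15 stand on more than 1 sample and none on more than 3, so the p-values measure the spread between these samples. In each of the 12 comparisons of a mutant with its fertile siblings, dye orientation was split 2 to 1 over the arrays.

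The deposited scanner files give the intensity of each spot in both channels, with its local background. They were made with Agilent Feature Extraction, version A.7.5.1 for the mac1 and ms23 arrays and version A.6.1.1 for the msca1 arrays, per the file headers. The A.7.5.1 files also hold the columns of a spatial detrending, which the A.6.1.1 files lack. The submitters' processing notes name limma and give no version. The deposited series matrix holds log2 values that the authors derived from the same arrays, with the scale and centring unstated. Set against the log2 scanner signal in the top decile of signal, its columns had slopes of 0.86 to 1.07 (median 0.96), so the values lie on a log2 scale. The column medians lay between -0.043 and 0.006 and the values between -1.54 and 8.63, so each column is centred close to 0. What else the authors did to these values stays unknown.

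The 72 scanner files hold 36 distinct arrays, each in 2 copies. Each of the 72 matrix columns correlated best, by Spearman's rho, with the array of the sample's label partner (lowest best rho 0.986). For 12 samples labelled with Cy5, 4 of mac1 and 8 of msca1, the file under the sample's own record is another array, with which the matrix column correlated at 0.947 at most. Both channels of every array were therefore read from the file of its Cy3 sample. Reading the Cy5 samples from their own file was tried as an alternative, on single-channel values without the array as block, since these files break the pairing.

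The arrays have 22575 features, of which 1612 are controls and 20963 are probes, each of 60 bases. Background was corrected with normexp (offset 50) on the mean signal and the median local background. Loess within each array followed, with controls and spots marked as outliers by the scanner software given weight 0, and limma 3.58.1 in R 4.3.3 was used throughout, with statmod 1.5.0. Controls were then left out. Spots marked as outliers were set to missing, which affected 7284 probes on at least 1 array, and received the fitted value in the gene list tests. A probe was tested if it was well above background in at least 3 of the 6 channels of at least 1 of the 12 comparisons. The 58 probes that failed this filter were removed, which left 20905.

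The log2 ratio of mutant over fertile was fitted on 36 arrays with 12 coefficients for mutant and stage and 1 common dye coefficient, which left 23 residual degrees of freedom for a probe without missing spots. Adjusted p-values are limma's moderated test with Benjamini-Hochberg adjustment over the tested probes of a comparison, and a probe was called at an adjusted p under 0.05. The error given with a log2 ratio is the standard error of that fit. Contrasts of the same fit gave the mean over 4 stages, the difference between mutants and the difference between stages. The fertile siblings at 2.0 mm were compared with those at 1.0 mm on single-channel log2 values after loess and Aquantile normalisation, over the fertile samples alone, with dye as covariate. Calls shared by a pair of mutants were tested with Fisher's exact test per stage and direction, with adjustment over the 24 tests. This test takes probes as independent, and the calls compared share the spread of each probe and the dye coefficient of 1 fit. The mutants have separate fertile siblings and share no array.

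Of the 20963 probes, 98 have a GenBank entry name as gene name, with 73 distinct entry names. A further 6178 have an accession, 14463 a contig of an expressed sequence assembly, and 224 an accession with a tag whose meaning is not given. Only 3 of the 6465 GenBank accessions matched a synonym in the reference table, so the names in the files were kept. For 55 of the 73 entry names the encoded product could be given from the entry name. The named genes of a mutant and stage were, in each direction, the 3 probes with the largest log2 ratio among called probes with an entry name. They also had the same sign on 3 of 3 arrays and were well above background on 3 arrays of the brighter group, with 1 probe per name. This rule took 27 named entries. It also takes up to 4 called members of a list that passed its test, those with the smallest adjusted p. The 3 mutated genes were to be reported first, but no probe carries their name.

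The groups, tests, alternatives, rule for named genes and 22 gene lists were fixed before the data were examined. Entry names were assigned to the lists after the names had been read and before any ratio had been computed. 2 lists had at least 5 tested probes, namely ribosomal proteins (7 probes) and transposable elements (26 probes, of the MuDR element). The MuDR probes are of 1 element, and some share bases or are reverse complements of each other, so they are not separate genes. They were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, with adjustment over the lists within a comparison. Another 9 lists had 1 to 4 members, which are reported singly: lipid transfer proteins, photosynthesis, heat shock proteins, flavonoid and anthocyanin, starch and sugar metabolism, peptidases and inhibitors, MADS-box genes, mature pollen genes, and redox and glutathione. The other 11 lists had no member, among them meiosis, tapetum regulators and pollen wall. The 200 probes that rose most and the 200 that fell most from 1.0 to 2.0 mm in the fertile siblings of each family, or as many as were called, formed stage lists. These were tested only in the mutants of the other families, so that the samples whose stages are compared for a list are not in its test. The spread and dye coefficient behind the calls came from the fertile samples of all families, so list and test are not fully separate.

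Same-numbered samples share an array, and their deviations from the group means correlated at 0.093 to 0.727, so the array was kept as the block in the ratio. The lowest of these 36 correlations is under 0.1, and the pairing rests on the shared array itself. The file headers give 6 days on which the scanner software was run (2 for mac1, 3 for ms23 and 1 for msca1), called extraction days here, which were used as a random block (consensus correlation 0.077) and as a fixed block, with a dye coefficient for each day. The plant code as a random block, on single-channel values without the array block, had a consensus correlation of 0.056. Other alternatives were the software's processed signal, centring each array on its median in place of loess, no filter, no dye coefficient, no array block, the arrays of the same mutant alone, the authors' matrix values, and leaving out each replicate in turn. A replicate number was left out of all mutants and stages at once. That also changes the spread, the residual degrees of freedom and the dye coefficient, so a changed call cannot be laid to 1 array of its comparison. After the data had been seen, 5 more were added: the Cy5 samples' own files, a filter within each comparison, arrays whose 2 plants share the first part of their source code, the extraction day in the fertile comparison, and the alternatives for the overlap of calls.

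The steps were tested on simulated data, with 50 probes changed by each of 4 sizes. Normal noise was drawn for each probe on its own, with the spread of the fit over all families. Correlation between probes, and a spread or dye effect particular to a family, were not simulated. The shares below hold for that setting and can overstate what these arrays give. In a simulation of mac1 at 1.5 mm over 20905 probes, 94% of probes changed by a log2 of 1 and 58% of those changed by 0.5 were called, as were 88% changed by -1 and 66% changed by -0.5, with 13 unchanged probes called. For the ms23 average these shares were 100%, 86%, 96% and 92%, with 5 unchanged probes called, and for the fertile mac1 comparison 86%, 18%, 68% and 26%, with 8. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The share of probes well above background per channel was 61.3% to 86.4% in the mac1 family, 57.5% to 87.0% in the ms23 family and 81.0% to 99.7% in the msca1 family, and the number of arrays limits the precision.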

Results

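Gene expression was compared in maize (Zea mays) between 3 male-sterile mutants and their fertile siblings. Anthers of mac1 form extra archesporial cells, the precursors of the meiocytes. The ms23 gene encodes a bHLH transcription factor needed for the tapetum, the inner wall layer that supplies the developing pollen. The msca1 gene encodes a glutaredoxin needed for archesporial cells to form at all. The mac1 family was in the A619 background and the other families in ND101. Whole spikelets and anthers of 1.0, 1.5 and 2.0 mm were sampled, in 24 groups of 3 samples, with 24 samples and 12 arrays per mutant. Between 61.3% and 86.4% of probes were well above background in a channel of the mac1 family, 57.5% to 87.0% in the ms23 family and 81.0% to 99.7% in the msca1 family. Of the 20905 tested probes, few carry a gene name: 98 probes of the array have an entry name. The mutated genes have no named probe, so their own transcripts are not reported. All values are log2 ratios of mutant over fertile on 3 arrays, unless another number is given, with limma's adjusted p. The error is that of the fit over 36 arrays, so it pools the spread of all groups and can lie below or above that of the 3 arrays. A fit without a replicate lacks the arrays of that number in all mutants and stages.

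The first question was which transcripts differ in mac1, where cell fate goes wrong inside the anther. At 1.5 mm, the transcript of chloroplast ribosomal protein L2 (CHZMRPL2P) rose by 1.46 ± 0.30 (adjusted p = 0.0031), a 2.76-fold difference. Glutamine synthetase (MZEGS1A), which assimilates ammonium, rose by 1.42 ± 0.37 (adjusted p = 0.016), and alpha-tubulin (ZMALTUB4), a subunit of microtubules, rose by 1.12 ± 0.25 (adjusted p = 0.0074). Pyruvate orthophosphate dikinase (MZEPOD), which makes phosphoenolpyruvate for carbon fixation, fell by 0.91 ± 0.21 (adjusted p = 0.007). Tryptophan synthase beta (MZEORP1A) fell by 0.88 ± 0.20 (adjusted p = 0.0079). At 1.0 mm ribosomal protein S28 (ZMRPS28) fell by 0.72 ± 0.13 (adjusted p = 0.0043), and at 2.0 mm protein disulfide isomerase (MZEPDI), which folds secreted proteins, fell by 0.82 ± 0.21 (adjusted p = 0.035). Each of these 7 probes moved the same way on 3 of 3 arrays, which the rule for named genes requires. With arrays centred on their median in place of loess, the calls of MZEPOD (adjusted p = 0.19), MZEORP1A (0.43) and ZMRPS28 (0.055) ended with the sign kept. Each call also ended without some replicates: CHZMRPL2P without replicate 1 (adjusted p = 0.073) or 2 (0.11), MZEGS1A without 1 (0.24) or 2 (0.088), ZMALTUB4 without 3 (0.14), MZEPOD without 1 (0.051) or 2 (0.19), MZEORP1A without 1, 2 or 3 (0.089, 0.087 and 0.085), ZMRPS28 without 1 (0.32) or 2 (0.27), and MZEPDI without 1 (0.34) or 2 (0.33). Without the array as a block the calls of MZEGS1A (adjusted p = 0.083), MZEPOD (0.15), ZMRPS28 (0.088) and MZEPDI (0.11) ended.

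The fixed lists large enough for a test were the MuDR transposon (26 probes) and ribosomal proteins (7). The MuDR probes cover both strands of 1 element and partly overlap, so their counts and list tests do not rest on independent members. At 1.5 mm 6 of 26 MuDR probes fell and none rose (8 fell adjusted over the list alone), and camera gave adjusted p = 0.0053 (adjusted p = 0.035 with an estimated correlation). The list's median was -0.02 and its mean -0.15. The probe with the largest decrease fell by 0.68 ± 0.17 (adjusted p = 0.012), and the 4 with the smallest adjusted p fell by 0.46 to 0.48. With median centring no MuDR probe was called at this stage, and the largest decrease became -0.24 (adjusted p = 0.46). Without replicate 2 or 3 that probe was not called either (adjusted p = 0.23 and 0.18), nor without the array as a block (0.23). In the other mac1 stages no MuDR probe was called, and the list gave adjusted p = 0.39 in spikelets, 0.19 at 1.0 mm and 0.4 at 2.0 mm. Of the 7 ribosomal protein probes, ZMRPS28 fell at 1.0 mm (2 fell adjusted over the list alone), with a median of -0.24 and adjusted p = 0.00055 (adjusted p = 0.065 with an estimated correlation). In spikelets no member was called (median -0.23, adjusted p = 0.016; adjusted p = 0.22 with an estimated correlation). At 1.5 mm 1 rose and 1 fell (adjusted p = 0.097), and at 2.0 mm none was called (adjusted p = 0.15), so the list passed at no mac1 stage with an estimated correlation. Under median centring the list's median turned to 0.15 in spikelets and 0.18 at 1.5 mm. Of the lists with few members, flavanone 3-hydroxylase (ZMFHT), an enzyme of flavonoid synthesis, fell by 0.60 ± 0.17 (adjusted p = 0.026) at 1.5 mm. A phospholipid transfer protein (MZEPLTP) fell by 0.46 ± 0.10 (adjusted p = 0.0048) at the same stage.

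Over all probes, mac1 had 2 calls in spikelets, both lower, 267 at 1.0 mm (173 higher and 94 lower), 1731 at 1.5 mm (1049 and 682) and 528 at 2.0 mm (171 and 357). At 1.0, 1.5 and 2.0 mm, 89, 185 and 173 of the calls exceeded 2-fold. Median centring moved the share of higher calls from 64.8% to 47.9% at 1.0 mm, from 60.6% to 90.5% at 1.5 mm, from 32.4% to 6.3% at 2.0 mm and from 0% to 100% of 1 call in spikelets, where the authors' matrix values gave 33.3% of 3. Leaving out replicate 1, 2 or 3 left 5, 0 and 20 calls in spikelets, 23, 23 and 457 at 1.0 mm, 304, 466 and 675 at 1.5 mm, and 37, 247 and 307 at 2.0 mm, where the arrays other than replicate 1 share an extraction day. Without the array as a block the counts were 87 at 1.0 mm, 369 at 1.5 mm and 192 at 2.0 mm. A fit of the mac1 arrays alone gave 0, 139, 2737 and 713. The extraction day as a fixed block left 267 at 2.0 mm and ended the call of MZEPDI (adjusted p = 0.13).

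**Figure D1:**
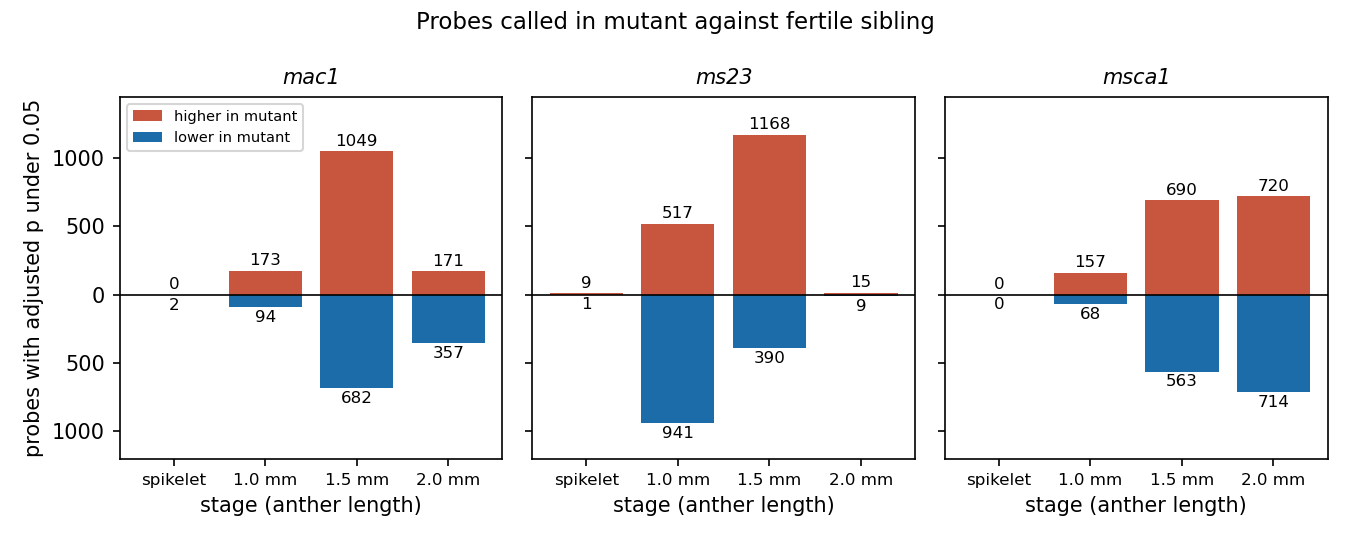
Bars give the number of probes with an adjusted p under 0.05 that were higher (upward) or lower (downward) in the mutant, by stage, for each of 3 mutants. In mac1 the bars are tallest at 1.5 mm (1049 higher and 682 lower), a split that median centring turns to 90.5% higher.

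In ms23, where the tapetum fails, the chloroplast ribosomal protein L2 transcript (CHZMRPL2P) was again higher at 1.5 mm. It rose by 1.98 ± 0.30 (adjusted p = 0.00021), a 3.94-fold difference, and stayed called without each replicate in turn. Sucrose phosphate synthase (MZESUCPHO), which makes sucrose, rose by 0.24 ± 0.06 (adjusted p = 0.024), and ZMRNCAL, whose product the name does not give, rose by 0.39 ± 0.11 (adjusted p = 0.027). The MZESUCPHO probe was dim, at log2 levels of 6.86 in fertile and 7.11 in mutant samples. Ribosomal proteins L39 (ZMRPL39) and S21 (ZM40SS21) fell by 1.00 ± 0.18 (adjusted p = 0.002) and by 0.89 ± 0.14 (adjusted p = 0.00035), and ZML32, of unstated product, fell by 0.94 ± 0.22 (adjusted p = 0.0084). At 1.0 mm tryptophan synthase beta (MZEORP1A) fell by 0.80 ± 0.20 (adjusted p = 0.021). Phenylalanine ammonia-lyase (MZEPAL), the entry to phenylpropanoid synthesis, fell by 0.69 ± 0.15 (adjusted p = 0.0087), and a MADS-box protein (MZEMADSB) fell by 0.67 ± 0.15 (adjusted p = 0.0092). On replicates 1 to 3 MZEPAL had -1.37, -0.22 and -0.51, and MZEMADSB had -1.46, -0.27 and -0.43. Replicate 1 thus carried much of both falls. The standard deviations of these arrays, 0.60 and 0.65, are wider than the pooled errors convey. Under median centring the calls at 1.0 mm ended: MZEMADSB turned to 0.10 (adjusted p = 0.7), MZEPAL moved to -0.10 (0.61) and MZEORP1A to -0.01 (0.98). At 1.5 mm it ended those of ZMRPL39 (adjusted p = 0.064), ZM40SS21 (0.086), ZML32 (0.24), ZMRNCAL (0.31) and MZESUCPHO (0.053). Calls ended without replicate 1, 2 or 3 for MZEORP1A (adjusted p = 0.11, 0.12 and 0.37), ZMRNCAL (0.1, 0.083 and 0.31) and MZESUCPHO (0.14, 0.26 and 0.16). They ended without 1 or 3 for MZEPAL (0.27 and 0.2), MZEMADSB (0.42 and 0.24), ZMRPL39 (0.075 and 0.23) and ZML32 (0.17 and 0.16), and without 3 for ZM40SS21 (0.14). Without the array as a block the calls of MZEORP1A (adjusted p = 0.14), MZEPAL (0.45), MZEMADSB (0.27), ZMRNCAL (0.14) and MZESUCPHO (0.52) ended.

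As a list, ribosomal proteins had negative medians in ms23 anthers, except at 1.0 mm under median centring. At 1.5 mm 3 of 7 fell and 1, CHZMRPL2P, rose (6 fell adjusted over the list alone), with a median of -0.76 and adjusted p = 0.00014 (adjusted p = 0.041 with an estimated correlation). ZMRPS28 was the third that fell, by 0.76 ± 0.13 (adjusted p = 0.0011). At 1.0 mm 3 passed as lower, of which ZMRPS28 was measured on 1 array (-0.87), so that 2 calls have replicates (4 adjusted over the list alone), with a median of -0.42, adjusted p = 0.0034 and adjusted p = 0.12 with an estimated correlation, and under median centring the median turned to 0.34. ZMRPL39 fell by 0.63 ± 0.18 (adjusted p = 0.038) and ZM40SS21 by 0.47 ± 0.14 (adjusted p = 0.042, with this sign on 2 of 3 arrays). At 2.0 mm no member was called (median -0.20, adjusted p = 0.023; adjusted p = 0.13 with an estimated correlation), nor in spikelets (median 0.02, adjusted p = 0.4). Of the MuDR probes 3 fell at 1.5 mm (3 adjusted over the list alone), by 0.30 to 0.56, with adjusted p = 0.026 and adjusted p = 0.071 with an estimated correlation. At 1.0 mm 4 fell (5 adjusted over the list alone; adjusted p = 0.19, with a median of 0.01 and a mean of -0.07), and under median centring none was called at either stage. In spikelets and at 2.0 mm none was called (adjusted p = 0.19 and 0.052). At 1.0 mm pyruvate orthophosphate dikinase (MZEPOD) fell by 1.50 ± 0.25 (adjusted p = 0.0014, 2 arrays). Profilin ZMPRO3MR, an actin-binding protein of the mature pollen list, fell by 0.33 ± 0.09 (adjusted p = 0.023), and MZEPLTP fell by 0.34 ± 0.10 (adjusted p = 0.041, with this sign on 2 of 3 arrays).

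The number of calls in ms23 was 10 in spikelets (9 higher, 1 lower), 1458 at 1.0 mm (517 and 941), 1558 at 1.5 mm (1168 and 390) and 24 at 2.0 mm (15 and 9), of which 83, 160 and 7 in anthers exceeded 2-fold. Median centring moved the share of higher calls from 35.5% to 78.6% at 1.0 mm, from 75% to 90.1% at 1.5 mm and from 62.5% to 100% of 4 calls at 2.0 mm, where the matrix values gave 28.6% of 7. The processed signal moved that share from 90% to 30.3% of 33 in spikelets. Leaving out replicate 1, 2 or 3 left 1, 25 and 1 calls in spikelets, 69, 1347 and 3 at 1.0 mm, 300, 500 and 864 at 1.5 mm, and 0, 163 and 7 at 2.0 mm. The arrays left without replicate 3 at 1.5 mm, and those left without replicate 1 at 2.0 mm, share an extraction day. The counts were lower without the array as a block, with 1 in spikelets, 63 at 1.0 mm, 401 at 1.5 mm and 9 at 2.0 mm. In a fit of the ms23 arrays alone they were 0, 85, 233 and 0, so most calls depend on fitting the other families' arrays too. That fit changes the spread, the residual degrees of freedom and the dye coefficient at once, and these were not separated. CHZMRPL2P alone of the 9 entries named first then stayed called (adjusted p = 0.018). The extraction day as a fixed block left 733 calls at 1.5 mm, with 30.5% of the 1558 kept, and ended those of ZMRNCAL (adjusted p = 0.28), MZESUCPHO (0.23) and ZML32 (0.14).

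In msca1, which lacks archesporial cells, the calls are of single named transcripts, since the lists of sugar (4 probes) and redox enzymes (3) were too small for a list test. Sucrose phosphate synthase (MZESUCPHO) rose by 0.29 ± 0.06 at 1.5 mm (adjusted p = 0.0067) and sucrose synthase (MZESUS1A), which cleaves sucrose, by 0.61 ± 0.15 at 2.0 mm (adjusted p = 0.014). Mitochondrial manganese superoxide dismutase (MZEMTMSODA), which removes superoxide, rose by 0.60 ± 0.13 at 1.0 mm (adjusted p = 0.025). ZMRNCAL rose by 0.42 ± 0.11 (adjusted p = 0.021) and a MuDR probe by 0.33 ± 0.09 (adjusted p = 0.032) at 2.0 mm. MZESUCPHO, MZESUS1A and the MuDR probe had the lowest fertile levels of the 27 named entries. Their log2 levels in fertile and mutant samples were 6.32 and 6.62, 6.57 and 7.18, and 5.95 and 6.31. These rises of 1.22, 1.53 and 1.26-fold are therefore of dim probes. The beta subunits of tryptophan synthase fell at 1.5 mm, MZEORP1A by 0.83 ± 0.20 (adjusted p = 0.014) and MZEORP2A by 0.48 ± 0.14 (adjusted p = 0.04). ZML32 fell by 1.06 ± 0.22 at 1.5 mm (adjusted p = 0.0035) and by 0.92 ± 0.22 at 2.0 mm (adjusted p = 0.01), where ZMRPS28 fell by 0.51 ± 0.13 (adjusted p = 0.023). Median centring kept these signs and ended the calls of MZEMTMSODA (adjusted p = 0.13), MZESUCPHO (0.089), MZEORP1A (0.2), MZEORP2A (0.55), ZMRNCAL (0.86), ZMRPS28 (0.079) and ZML32 (0.15 at 1.5 mm and 0.065 at 2.0 mm). Calls ended without replicate 1, 2 or 3 for MZEORP2A (0.28, 0.19 and 0.08), the MuDR probe (0.33, 0.099 and 0.22) and ZML32 at 1.5 mm (0.051, 0.069 and 0.078). They ended without 2 or 3 for MZEMTMSODA (0.27 and 0.095), MZESUCPHO (0.14 and 0.18), ZML32 at 2.0 mm (0.17 and 0.092) and ZMRPS28 (0.28 and 0.12). They ended without 1 or 2 for MZEORP1A (0.29 and 0.1) and MZESUS1A (0.13 and 0.12), and without 1 or 3 for ZMRNCAL (0.19 and 0.36). Taking away the array block ended 7 calls: MZEMTMSODA (adjusted p = 0.8), MZESUCPHO (0.35), MZEORP2A (0.32), MZESUS1A (0.11), ZMRNCAL (0.091), the MuDR probe (0.18) and ZMRPS28 (0.18). Read from the Cy5 samples' own files, without the array block, the values at 1.5 mm turned sign for MZESUCPHO (-0.03), ZML32 (0.32), MZEORP1A (0.04) and MZEORP2A (0.05).

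Ribosomal proteins had a lower median in msca1 at each stage, under each scaling tried. At 1.0 mm none of 7 was called over all probes and 2 fell adjusted over the list alone (median -0.42, adjusted p = 0.00024; adjusted p = 0.049 with an estimated correlation). At 1.5 mm none was called over all probes and 6 fell adjusted over the list alone (median -0.41, adjusted p = 0.0025; adjusted p = 0.11 with an estimated correlation). At 2.0 mm ZMRPS28 and ZMRPL39 fell, the latter by 0.79 ± 0.22 (adjusted p = 0.032, 2 arrays), and 4 fell adjusted over the list alone (median -0.51, adjusted p = 0.0015; adjusted p = 0.092 with an estimated correlation). In spikelets none was called (median -0.17, adjusted p = 0.21). The MuDR list gave adjusted p = 0.21 in spikelets, 0.86 at 1.0 mm, 0.18 at 1.5 mm and 0.23 at 2.0 mm, with no call but the probe named for 2.0 mm (1 adjusted over the list alone). Over the 3 mutants, the cystatin of the peptidase inhibitor list and the heat shock protein were not called at any stage, though the latter, alone in its list, had an unadjusted p under 0.05 as lower in mac1 at 1.5 mm. The photosystem protein ZEAOE17 was not called over all probes and passed as higher only adjusted over its list of 2, in mac1 and in ms23 at 1.5 mm.

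The count of calls in msca1 was 0 in spikelets by limma (1111 probes at an unadjusted p under 0.05), 225 at 1.0 mm (157 higher and 68 lower), 1253 at 1.5 mm (690 and 563) and 1434 at 2.0 mm (720 and 714). Of these, 99, 384 and 478 in anthers exceeded 2-fold. Median centring moved the share of higher calls at 1.0 mm from 69.8% to 83.7%. Leaving out replicate 1, 2 or 3 left 0, 2 and 3 calls in spikelets, 90, 46 and 95 at 1.0 mm, 397, 352 and 470 at 1.5 mm, and 651, 456 and 1007 at 2.0 mm. Of the 2.0 mm calls, 90.9%, 90.4% and 65% had the same sign on the array left out. Replicates 1 and 2 have 1 dye orientation there and replicate 3 the opposite one. Log ratios correlated at 0.46 between replicates 1 and 2, and at 0.45 and 0.51 with replicate 3. A dye effect in these calls was not tested. Without the array as a block the counts were 1 in spikelets, 92 at 1.0 mm, 455 at 1.5 mm and 612 at 2.0 mm. A fit of the msca1 arrays alone gave 1, 367, 1404 and 1613, and ended the calls of MZEMTMSODA (adjusted p = 0.059), MZEORP1A (0.063), MZEORP2A (0.083) and ZMRPS28 (0.053). All msca1 arrays share 1 extraction day. With the Cy5 samples read from their own file, which is another array for 8 of them, and without the array as a block, the counts were 1, 0, 37 and 3, to be set beside the 1, 92, 455 and 612 without the block alone.

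**Figure D2:**
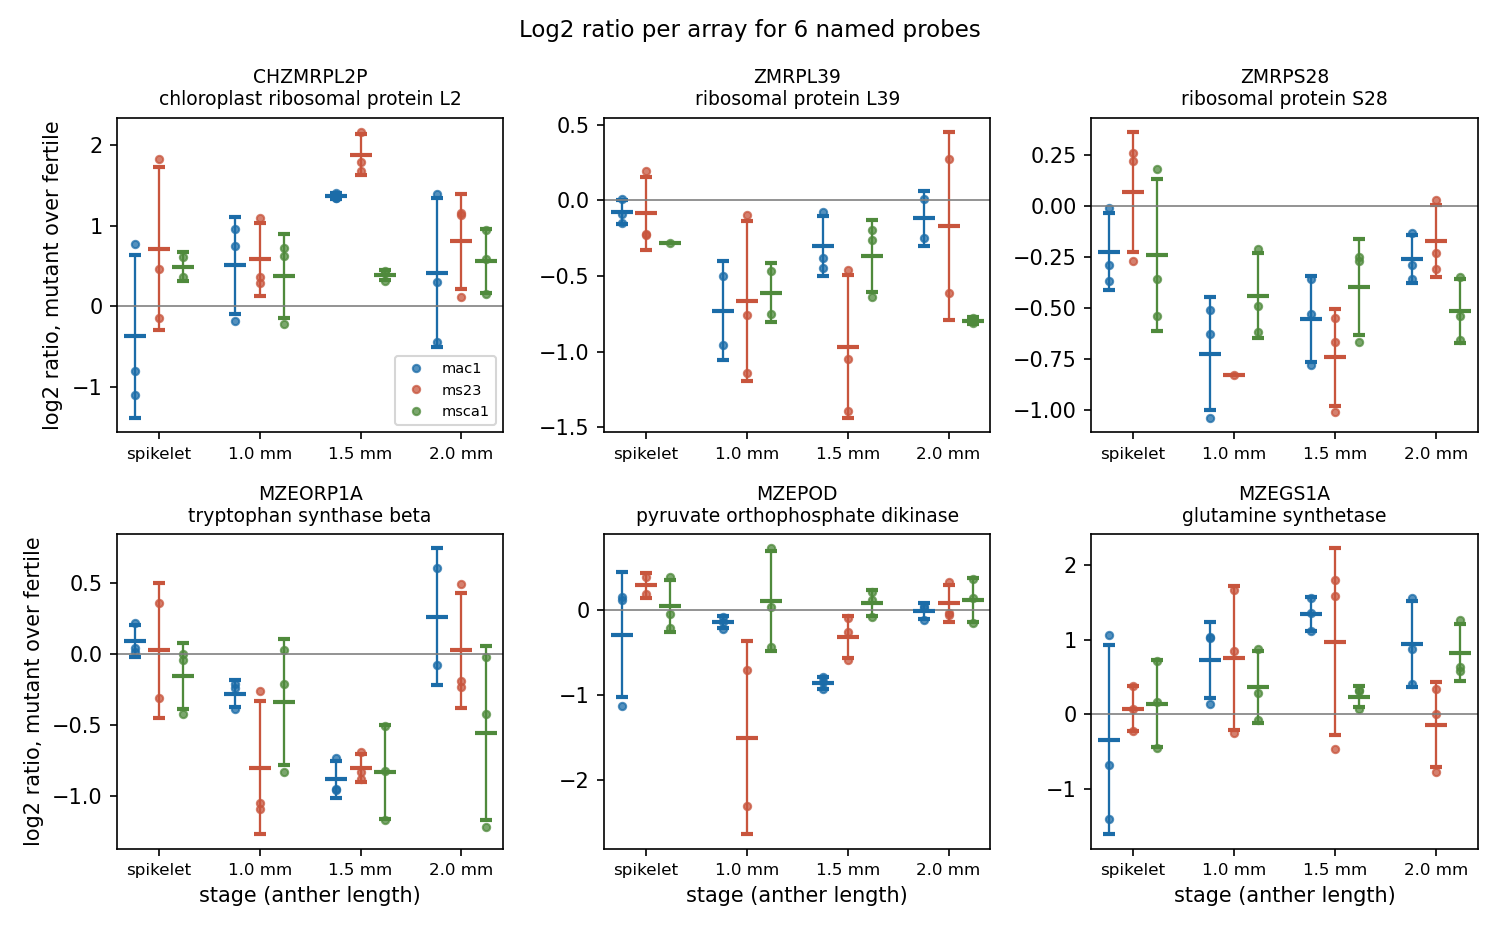
Points are the log2 ratio of mutant over fertile on each array, bars the mean and standard deviation, for 6 named probes by stage (horizontal axis) and mutant (colour). CHZMRPL2P is above 0 on 3 of 3 ms23 arrays at 1.5 mm, as the rule for named genes requires, and its fitted log2 ratio there is 1.98. ZMRPS28 is mostly below 0, with a fitted value of -0.72 in mac1 at 1.0 mm.

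Averaged over 4 stages, several named transcripts moved alike in the 3 mutants. ZMRPS28 fell by 0.44 ± 0.07 in mac1 (12 arrays; adjusted p = 0.00022), by 0.43 ± 0.08 in ms23 (10 arrays; adjusted p = 0.0019) and by 0.40 ± 0.07 in msca1 (12 arrays; adjusted p = 2e-04). ZML32 fell by 0.40 ± 0.11 (adjusted p = 0.034), 0.60 ± 0.11 (adjusted p = 0.00098) and 0.77 ± 0.11 (adjusted p = 2.2e-05) in that order. CHZMRPL2P rose by 0.48 ± 0.15 (adjusted p = 0.045), 1.00 ± 0.15 (adjusted p = 0.00015) and 0.50 ± 0.16 (adjusted p = 0.032). At single stages CHZMRPL2P was called as higher in mac1 and in ms23 at 1.5 mm alone, and in msca1 at no stage. The ribosomal list had a median of -0.29 in mac1 (1 fell and 1 rose; 5 fell adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.047 with an estimated correlation). In ms23 3 fell and 1 rose (median -0.40, 6 fell adjusted over the list alone, adjusted p = 0.00035; adjusted p = 0.056 with an estimated correlation). In msca1 6 of 7 fell and 1 rose (median -0.40, 6 fell adjusted over the list alone, adjusted p = 0.00017; adjusted p = 0.044 with an estimated correlation). Of the MuDR probes 4 fell in mac1 (7 adjusted over the list alone; adjusted p = 0.0098, and adjusted p = 0.047 with an estimated correlation), 1 fell in ms23 (adjusted p = 0.072) and 1 rose in msca1 (adjusted p = 0.15), and median centring left none of them called. In mac1 MZEPAL fell by 0.34 ± 0.08 (adjusted p = 0.0067) and MZEPLTP by 0.24 ± 0.05 (adjusted p = 0.0035). In msca1 MZESUS1A rose by 0.36 ± 0.08 (adjusted p = 0.0018), with this sign on 12 of 12 arrays, and MZEORP1A fell by 0.47 ± 0.10 (adjusted p = 0.0024).

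In total 1627 probes were called in the mac1 average (821 higher and 806 lower), 2118 in ms23 (1333 and 785) and 3006 in msca1 (1535 and 1471), and 156 were called the same way in all 3 averages (93 higher and 63 lower). Median centring moved the share of higher calls from 50.5% to 68% in mac1 and from 62.9% to 86.7% in ms23, where the matrix values gave 50.4%. Leaving out replicate 1, 2 or 3 left 372, 590 and 579 calls in mac1, 271, 1458 and 1030 in ms23, and 1460, 1158 and 2358 in msca1. With no array block the counts were 397, 537 and 1533, and with the plant code as a random block in place of the array they were 333, 473 and 1481. From the arrays of the same mutant alone they were 2523, 395 and 2977, and the extraction day as a fixed block gave 1813, 1165 and 3360.

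Probes without a name were also called alike in the 3 averages. Of the assembly probes among them, the 2 with the largest mean change in each direction are given, a choice made after the values were seen. They are named by their sequence. In the order given below, the called sign was on 11, 10, 12 and 12 of 12 arrays in mac1, on 9, 9, 8 and 8 in ms23, and on 11, 9, 10 and 12 in msca1. The probe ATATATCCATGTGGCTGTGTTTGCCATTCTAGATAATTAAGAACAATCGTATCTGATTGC fell by 3.53 ± 0.26 in the msca1 average (adjusted p = 2.6e-09), by 1.45 ± 0.24 in mac1 (adjusted p = 6e-04) and by 1.42 ± 0.24 in ms23 (adjusted p = 0.00065). In msca1 at 2.0 mm it fell by 5.31 ± 0.49 (adjusted p = 4.7e-07). The probe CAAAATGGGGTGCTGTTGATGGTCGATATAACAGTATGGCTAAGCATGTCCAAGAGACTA fell by 3.16 ± 0.43 in the mac1 average (adjusted p = 3.7e-05), and at 1.5 mm in mac1 it fell by 5.54 ± 0.86 (adjusted p = 0.00021). In the other direction, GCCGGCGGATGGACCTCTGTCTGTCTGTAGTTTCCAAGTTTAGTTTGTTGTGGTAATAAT rose by 1.05 ± 0.22 in mac1 (adjusted p = 0.0038), 0.70 ± 0.22 in ms23 (adjusted p = 0.04) and 1.23 ± 0.22 in msca1 (adjusted p = 0.00027). Likewise, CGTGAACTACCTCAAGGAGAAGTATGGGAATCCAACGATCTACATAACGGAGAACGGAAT rose by 0.69 ± 0.19 (adjusted p = 0.027), 0.67 ± 0.19 (adjusted p = 0.026) and 1.1 ± 0.19 (adjusted p = 0.00025) in that order.

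Tests of the difference between mutants asked where the effects of the mutations differ. The difference mac1 minus msca1 at 1.5 mm was -1.02 ± 0.24 for flavanone 3-hydroxylase ZMFHT (adjusted p = 0.01), -0.54 ± 0.14 for MZEPLTP (adjusted p = 0.02), -0.74 ± 0.21 for MZEPAL (adjusted p = 0.038) and 1.34 ± 0.35 for alpha-tubulin ZMALTUB4 (adjusted p = 0.025). The difference ms23 minus msca1 was -1.66 ± 0.33 for MZEPOD at 1.0 mm (adjusted p = 0.018, on 2 ms23 arrays), 0.76 ± 0.20 for MZEORP2A at 1.5 mm (adjusted p = 0.039) and -0.91 ± 0.21 for MZESUS1A at 2.0 mm (adjusted p = 0.036). Between stages, the ms23 effect on MZEPOD was higher by 1.63 ± 0.33 at 2.0 than at 1.0 mm (adjusted p = 0.018), with 2 arrays at 1.0 mm. The ms23 arrays of these stages share no extraction day, so stage and day cannot be told apart. The entries given here are those whose difference was called and whose product the name gives. Averaged over stages, ms23 minus msca1 had 1044 calls (694 higher and 350 lower; 81.2% higher under median centring against 66.5%), mac1 minus ms23 130 (56 and 74; 53.5% higher in the matrix values against 43.1%) and mac1 minus msca1 1274 (726 and 548). Differences with mac1 are confounded with the genetic background. Those with msca1 are confounded with the Feature Extraction version (A.6.1.1 against A.7.5.1), with the extraction day of msca1 and with its higher signal, a median of 96.8% of probes well above background against 74.2% in mac1 and 75.25% in ms23. Without replicate 1, 2 or 3 these counts were 268, 337 and 647, then 1, 91 and 82, then 231, 175 and 769, without the array as a block 244, 40 and 306, and with the extraction day as a fixed block 622, 59 and 1398.

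Calls shared by pairs of mutants addressed how alike the sterile anthers are, beyond the named genes. At 1.5 mm mac1 and ms23 shared 396 higher probes, against 58.6 for independent lists (Fisher's exact test, adjusted p = 1.81e-237), and 124 lower probes, against 12.7 (adjusted p = 1.04e-87). Under median centring 81.3% of these higher calls, and 13.7% of the lower, were made in both mutants. CHZMRPL2P is among the higher probes, and MZEORP1A, ZMRPS28 and 3 MuDR probes among the lower. At this stage ms23 and msca1 shared 137 higher probes (38.6 for independent lists; adjusted p = 3.1e-39), MZESUCPHO among them, and 67 lower (10.5; adjusted p = 7.1e-34), with ZML32. The pair mac1 and msca1 shared 53 lower probes (18.4; adjusted p = 1.46e-11), with MZEORP1A, and 27 higher ones (34.6; adjusted p = 0.321). At 2.0 mm that pair shared 50 higher (5.9; adjusted p = 5.56e-32) and 77 lower probes (12.2; adjusted p = 6e-39). Of the 24 tests 12 passed, and 8, 11 and 8 without replicate 1, 2 or 3. Probes are not independent of each other, and both lists of a pair come from 1 fit with a shared spread and dye coefficient. The p-values of Fisher's exact test are therefore too small by an unknown amount, and the shared counts are descriptive.

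**Figure D3:**
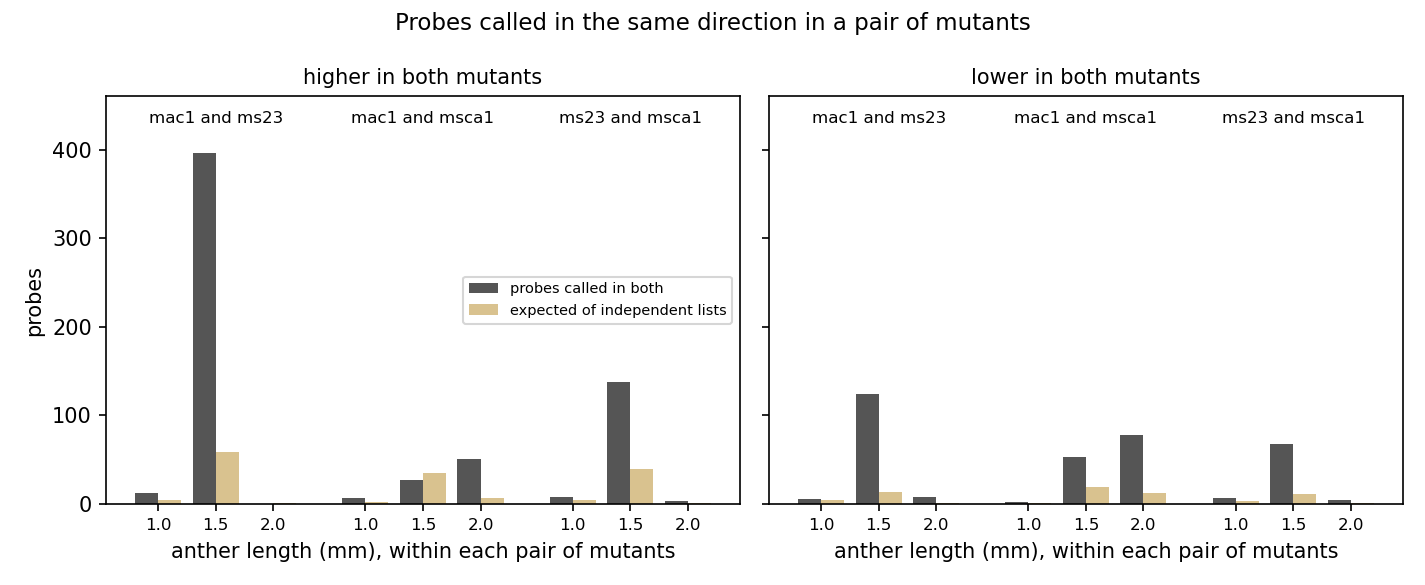
Bars give the number of probes called in the same direction in a pair of mutants (dark) and the number for independent lists of those sizes (light), by anther length in mm, for higher and lower probes. The tallest pair of bars is that of mac1 and ms23 at 1.5 mm, with 396 shared higher probes against 58.6, and median centring keeps 81.3% of the shared higher calls and 13.7% of the lower.

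The fertile siblings were compared to find transcripts that change as anthers grow. From 1.0 to 2.0 mm the oxygen-evolving protein ZEAOE17, part of photosystem II, rose by 1.25 ± 0.27 in the mac1 family (adjusted p = 0.0094) and by 1.62 ± 0.27 in the ms23 family (adjusted p = 0.00058). Ribosomal protein L39 (ZMRPL39) fell by 1.43 ± 0.29 (adjusted p = 0.0094) and 1.57 ± 0.26 (adjusted p = 0.0011), and S28 (ZMRPS28) fell by 0.93 ± 0.16 in the mac1 family (adjusted p = 0.0028). In the ms23 family S28 was measured on 1 array at 1.0 mm, so its fall there has no replicates. In the ms23 family MZEPOD fell by 1.90 ± 0.33 (adjusted p = 0.00093, with 2 arrays at 1.0 mm) and MZEMADSB by 0.99 ± 0.24 (adjusted p = 0.0091). In the msca1 family none of these was called: ZEAOE17 had 0.57 (adjusted p = 0.31), ZMRPL39 0.37 (0.56), ZMRPS28 -0.04 (0.93), MZEPOD 0.01 (0.99) and MZEMADSB -0.06 (0.94), and the difference between families was not tested. These entries were chosen after their values were seen. The fertile samples at 1.0 mm are also the fertile side of the mutant ratios at that stage. The falls of MZEPOD, MZEMADSB and ZMRPL39 in the ms23 family and their decreases in ms23 at 1.0 mm are therefore not separate results. The same holds for ZMRPS28 in mac1. The count was 820 in the mac1 family (436 higher and 384 lower at 2.0 mm), 2509 in ms23 (1287 and 1222) and 236 in msca1 (84 and 152). Without replicate 1, 2 or 3 it was 248, 428 and 275 in mac1, where the first value is within 1 extraction day, 433, 2520 and 344 in ms23, and 0, 323 and 22 in msca1. In the ms23 family extraction day and stage cannot be told apart, since 1.0 and 2.0 mm share no day. Of the 200 probes that rose most in ms23, 192 were higher at 2.0 mm in the mac1 family and 180 in msca1, and of the 200 that fell most, 175 and 169 were lower. For the lists of mac1, 184 of 200 rising probes were higher in the ms23 family and 166 in msca1, and 177 and 145 of 200 falling ones were lower. For the shorter lists of msca1, all its called probes, 60 of 84 rising probes were higher in mac1 and 64 in ms23, and 73 of 152 falling ones were lower in mac1 (48%) and 84 in ms23 (55.3%).

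Stage lists asked whether genes that change with anther growth differ in the mutants. In mac1 at 1.5 mm, 40 of the 200 probes that rise in ms23 fertile anthers rose and 4 fell (median 0.28, adjusted p = 3.1e-06; adjusted p = 0.46 with an estimated correlation). Of the 200 that fall, 38 fell and 1 rose (median -0.30, or 0.01 under median centring; adjusted p = 5.1e-12; adjusted p = 0.093 with an estimated correlation). At 2.0 mm, 29 of the rising probes fell and 5 rose in mac1 (median -0.29, adjusted p = 5.4e-07; adjusted p = 0.4 with an estimated correlation). In mac1 spikelets 184 of the 200 falling probes had negative values and none was called (median -0.24, or 0.04 under median centring; adjusted p = 3.6e-17; adjusted p = 0.029 with an estimated correlation). In ms23 at 1.0 mm 9 of the probes that rise in mac1 fertile anthers rose and none fell (median 0.24, adjusted p = 1.5e-06; adjusted p = 0.32 with an estimated correlation), while at 1.5 mm the median of that list was 0.02 (11 rose and 3 fell, adjusted p = 0.64), with 0.17, -0.26 and 0.18 on replicates 1 to 3. With the list of 436 probes the 1.5 mm median was 0.14 (51 rose and 4 fell, adjusted p = 6e-04; adjusted p = 0.78 with an estimated correlation). In ms23 at 2.0 mm the median was -0.19 for the probes that rise in mac1 fertile anthers (2 called lower, adjusted p = 9.2e-11) and 0.21 for those that fall (none called, adjusted p = 2e-10), each with adjusted p = 0.18 with an estimated correlation. Replicate 2 went the other way in both (0.29 and -0.23). In msca1 at 2.0 mm 26 of the falling mac1 probes fell and 4 rose (median -0.30, adjusted p = 9.2e-08; adjusted p = 0.57 with an estimated correlation), a shift of replicates 2 and 3 (replicate 1 had 0.05), and at 1.0 mm 3 fell (median -0.26, adjusted p = 2.6e-10; adjusted p = 0.26 with an estimated correlation). The rising lists went down in msca1 at 1.5 mm, where 29 of the mac1 probes fell and 8 rose (median -0.13). Of the ms23 probes 28 fell and 10 rose (median -0.21). Camera gave each adjusted p = 0.0053, and 0.9 with an estimated correlation. Of 48 such tests 26 passed at the preset correlation, 1 with an estimated correlation, the spikelet list of mac1, and 3 with fry.

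**Figure D4:**
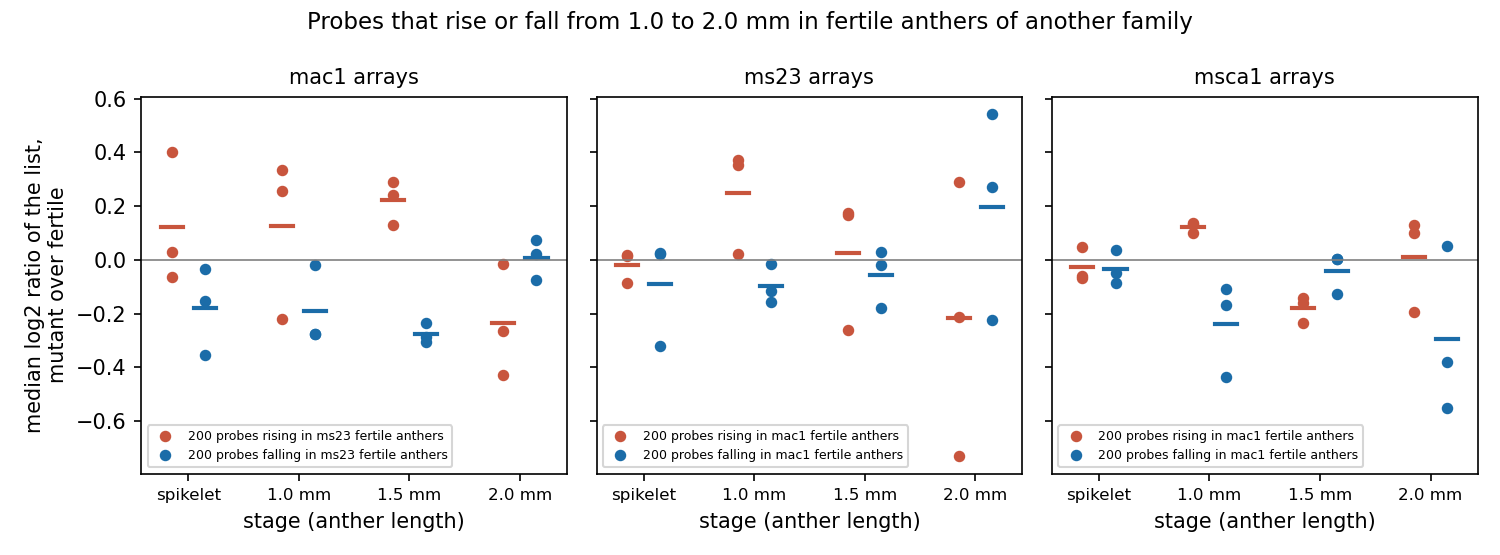
Points are the median log2 ratio of mutant over fertile on each array, lines their mean, for the probes that rise or fall most from 1.0 to 2.0 mm in the fertile anthers of another family, by stage and mutant. In mac1 at 1.5 mm the rising list lies above 0 on each array (0.24, 0.13 and 0.29) and the falling list below (-0.31, -0.29 and -0.24). The fitted ratios, adjusted for dye and not drawn, have medians of 0.28 and -0.30, and the latter turns to 0.01 under median centring.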

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

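The tests of mac1 at 1.0 mm (source codes, signal and dye), and those of ms23 at 2.0 mm on an array out of step and on low signal, were chosen only after the result was seen. The bound that would exclude low signal in mac1 at 1.0 mm was changed after its value had been seen.

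The effects of different mutants, and of a mutant at different stages, differed by a test of the difference itself in limma. The ms23 effect differed from the msca1 effect, averaged over stages, at 1044 probes, the mac1 effect from the ms23 effect at 130, and the mac1 effect from the msca1 effect at 1274. Between 2.0 and 1.0 mm the mac1 effect differed at 34 probes (7 higher and 27 lower), the ms23 effect at 202 (104 and 98) and the msca1 effect at 3 (3 and 0). Pyruvate orthophosphate dikinase (MZEPOD) is the named entry among these stage differences, in ms23, where it was measured on 2 arrays at 1.0 mm. The ms23 arrays of 1.0 and 2.0 mm share no extraction day, so stage and day cannot be told apart.

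The 520 probes called alike in mac1 and ms23 at 1.5 mm are the largest set of calls shared by a pair of mutants at a stage. A dye effect is argued against: of 283 probes called alike without the arrays of minority dye orientation, 89.1% had that sign on both left-out arrays. A bias with signal left by the loess stays open, since 65.2% of the shared calls were also made under median centring, 81.3% of those higher and 13.7% of those lower. A candidate explanation for the shared probes is that they are ahead in stage in both mutants: in the fertile msca1 siblings, which share no sample with either, 69.2% of the higher ones and 37.9% of the lower ones were higher at 2.0 than at 1.0 mm, against 53.5% of all tested probes, a difference of 31.3 points. Whether ms23 anthers run ahead in general stays open, since at 1.5 mm the rising mac1 list had a median of 0.02 in ms23 with 200 probes (adjusted p = 0.64) and 0.14 with 436 (adjusted p = 6e-04; adjusted p = 0.78 with an estimated correlation), and replicate 2 went against the other arrays.

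The count of mac1 at 1.0 mm depended on the replicate number left out. With 3 arrays 267 probes were called, 228 of them with the same sign on each. There were 23 calls without replicate 1 or 2, and 457 without replicate 3. These fits lack that replicate in the other comparisons too, so the counts cannot be laid to the mac1 arrays alone. The dye orientation of replicate 3 is argued against, since replicates 1 and 2, of opposite orientation, correlated more than the arrays of 1 orientation, by 0.41 (0.72 against 0.31). Low signal on replicate 3 stays open, since its share of probes well above background, 68.3%, was the lowest of the 3, -5.5 points from the next (73.8%), less than the 10 points set for the test. A difference between the plants, whose source codes start differently on replicates 1 and 2, stays open too: of the 442 probes called without replicate 3 and measured on it, 71% had the same sign there, between the bounds set. No biological explanation was tested.

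ms23 had 24 calls at 2.0 mm and 1558 at 1.5 mm. Low signal is argued against, since the median share of probes well above background was 8.4 points above that of mac1 at 1.5 mm (81.4% against 73%). A smaller effect may explain it: the probes called at 1.5 mm had a median change of 0.56 there and 0.11 at 2.0 mm, a ratio of 0.20, while the arrays left out at 1.5 mm still gave 0.55, 0.41 and 0.35. An array out of step stays open, since the highest correlation between 2 arrays, replicates 1 and 3, was 0.31, between the bounds set. Replicate 2 correlated with them at 0.02 and -0.19, and of 163 probes called without it 44.8% had the same sign on it, while of the probes called at 1.5 mm it was replicate 3 that had no median change (-0.01).

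Other splits of the samples were counted for every comparison. The 6 samples of a mutant and stage make 10 splits, too few for a share under 0.05, so each result is set beside the highest other split. In mac1 the real split gave 2 calls in spikelets (highest other 425; 10 of 10 splits as large), 267 at 1.0 mm (48), 1731 at 1.5 mm (3) and 528 at 2.0 mm (445), with 1 split as large, the real one, at these 3 stages. In ms23 it gave 10 in spikelets (283; 8 of 10 splits), 1458 at 1.0 mm (1883; 3 splits), 1558 at 1.5 mm (53; 1 split) and 24 at 2.0 mm (270; 8 splits). In msca1 it gave 0 in spikelets (736; 10 splits), 225 at 1.0 mm (26), 1253 at 1.5 mm (91) and 1434 at 2.0 mm (1070), with 1 split as large in anthers. The fertile comparisons gave 820 in mac1 (70), 2509 in ms23 (38) and 236 in msca1 (2), again with 1 split as large. Among splits that part 3 pairs, as the real one does, the highest other counts were 12 in mac1 and 106 in ms23 at 2.0 mm, 33 in ms23 at 1.0 mm and 1070 in msca1 at 2.0 mm, and the remaining splits part 1 pair and rest on 1 array. The 1883 calls of ms23 at 1.0 mm came from splits that rest on replicate 1 alone. Counts several times the real one point to a structure of the samples, whose source was not tested. Spikelet arrays of opposite dye orientation had log ratios correlated at -0.2 and -0.23 in mac1, -0.2 and -0.05 in ms23, and -0.06 and -0.11 in msca1. Those of 1 orientation correlated at 0.25, 0 and 0.34. A dye effect left by the common dye coefficient was not tested there. In ms23 at 1.0 mm the order was the reverse, with 0.36 and 0.2 for opposite orientations against 0.06. The 283 and 736 in ms23 and msca1 spikelets and the 270 in ms23 at 2.0 mm came from splits that rest on 1 array, and the 425 in mac1 spikelets from a split that parts 3 pairs.

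For averages and differences 100 splits were drawn each, by turning the sign of whole arrays for an average and by exchanging arrays of a stage between mutants for a difference. The averages gave 1627 in mac1 (highest other 825, 1 split as large) and 3006 in msca1 (highest other 2430, 1 split). In ms23 3 splits, the real one included, gave at least 2118 (highest other 2388). These shares are under 0.05, which makes a chance result unlikely and does not exclude it. In the 2 other splits that were as large in ms23, the 6 arrays of 1.0 and 1.5 mm were turned 1 way. The differences gave 1044 for ms23 minus msca1 (highest other 61), 130 for mac1 minus ms23 (4) and 1274 for mac1 minus msca1 (154). In each, 1 split was as large, the real one. The exchanged arrays are of families that also differ in background, extraction day or software version. The low counts of the other splits therefore show that the families differ, and not that the mutations are the source.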

How the results depend on the processing

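The filter within each comparison, the Cy5 samples' own files, the arrays of 1 source-code prefix, the extraction day in the fertile comparisons and the alternatives for shared calls were chosen after the data were seen. Counts moved by more than 1.5 times most often without replicate 1 (21 counts moved and 2 did not), 2 (17 and 6) or 3 (20 and 3), without the array block (18 and 2), and with the Cy5 samples' own files (20 and 0), a setting that also lacks the array block. The sign of a named entry turned in 5 cases, given below by name. Testing without a filter, with a filter within the comparison, with all channels quantile normalised, with stage lists of 100 or 500 probes (24 and 27 tests passed against 26), or with the extraction day as a random block in the fertile comparisons moved no count by more than 1.5 times. The signal over background limits all of this: as few as 57.5% of probes were well above it in a channel, and a dim probe's ratio is drawn toward 0 by the offset. The cause was not tested for any move below, except that fewer arrays leave less to test with.

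Leaving out 1 replicate number in turn, from all mutants and stages at once, gave these lowest and highest counts. In mac1 they were 0 and 20 in spikelets (2 with all arrays), 23 and 457 at 1.0 mm (267), 304 and 675 at 1.5 mm (1731), and 37 and 307 at 2.0 mm (528). In ms23 they were 1 and 25 (10), 3 and 1347 (1458), 300 and 864 (1558), and 0 and 163 (24). In msca1 they were 0 and 3 (0), 46 and 95 (225), 352 and 470 (1253), and 456 and 1007 (1434). The averages gave 372 and 590 in mac1 (1627), 271 and 1458 in ms23 (2118), and 1158 and 2358 in msca1 (3006). The differences gave 268 and 647 for ms23 minus msca1 (1044), 1 and 91 for mac1 minus ms23 (130), and 175 and 769 for mac1 minus msca1 (1274). Tests of shared calls passed in 8 and 11 cases (12), and 8 of 27 named entries stayed called without replicate 1, 8 without 2 and 8 without 3. The fertile comparisons gave 248 and 428 in mac1 (820), 344 and 2520 in ms23 (2509), and 0 and 323 in msca1 (236).

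Without the array as a replicate block the pairing is lost. The counts were 87, 369 and 192 in mac1 anthers of 1.0, 1.5 and 2.0 mm, then 1, 63, 401 and 9 in ms23 from spikelets to 2.0 mm, and 1, 92, 455 and 612 in msca1. They were 397, 537 and 1533 for the averages of mac1, ms23 and msca1, 244 for ms23 minus msca1, 40 for mac1 minus ms23 and 306 for mac1 minus msca1. Of the named entries 10 stayed called. The block changed no other count by more than 1.5 times. The plant code as a random block, in the same fit without the array block, gave 333, 473 and 1481 for the averages.

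The processed signal gave 3507 calls in mac1 at 1.5 mm, 33, 3149 and 3 in ms23 in spikelets and at 1.0 and 2.0 mm, 81 and 737 in msca1 at 1.0 and 1.5 mm, 2962 in the mac1 average and 1916 in the msca1 average. Median centring gave 1 in mac1 spikelets, 1, 4152 and 4 in ms23 in spikelets and at 1.0 and 2.0 mm, 104, 519 and 720 in msca1 at 1.0, 1.5 and 2.0 mm, 556 and 1767 in the mac1 and msca1 averages and 381 in mac1 minus msca1. It left 7 named entries called and turned MZEMADSB in ms23 at 1.0 mm to 0.10. The authors' matrix values gave 3, 1022 and 7 in ms23 in spikelets and at 1.5 and 2.0 mm, and 821 in msca1 at 2.0 mm.

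Without a dye coefficient the counts were 0 in mac1 spikelets, 1080 in mac1 at 1.5 mm, and 0, 1032 and 12 in ms23 in spikelets and at 1.5 and 2.0 mm. The arrays of the same mutant alone gave 0, 139 and 2737 in mac1 in spikelets and at 1.0 and 1.5 mm, 2523 in its average, 0, 85, 233 and 0 in ms23 over the 4 stages, 395 in its average, and 1 and 367 in msca1 in spikelets and at 1.0 mm, with 14 named entries called. With the extraction day as a random block the counts were 10 in mac1 spikelets, 37 in ms23 at 2.0 mm and 6 in msca1 spikelets. As a fixed block, which gives each day its own dye coefficient, it gave 13 and 267 in mac1 in spikelets and at 2.0 mm, 733 and 37 in ms23 at 1.5 and 2.0 mm, 2 in msca1 spikelets, 1165 in the ms23 average, 622 for ms23 minus msca1 and 59 for mac1 minus ms23.

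Reading the Cy5 samples from their own file was done in the fit without the array block, so 2 choices changed at once and the counts without the block are the like comparison. The file differs for 4 samples of mac1 and 8 of msca1 and for none of ms23, whose own data are therefore unchanged. The counts were 0, 47, 229 and 9 in mac1 from spikelets to 2.0 mm, 0, 45, 186 and 1 in ms23, and 1, 0, 37 and 3 in msca1. The averages gave 160, 330 and 0, and the differences 2 (ms23 minus msca1), 8 (mac1 minus ms23) and 4 (mac1 minus msca1). Of 24 tests of shared calls 2 passed, and 2 named entries stayed called. In msca1 at 1.5 mm MZESUCPHO turned to -0.03, ZML32 to 0.32, MZEORP1A to 0.04 and MZEORP2A to 0.05. Arrays of 1 source-code prefix gave 13, 7 and 112 in mac1 in spikelets and at 1.0 and 2.0 mm, 599, 898 and 14 in ms23 at 1.0, 1.5 and 2.0 mm, 3 in msca1 spikelets, 308 in the mac1 average, 494 for ms23 minus msca1, 34 for mac1 minus ms23 and 597 for mac1 minus msca1.

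With an estimated correlation 6 of 30 gene list tests passed against 14 at the preset one, and 1 of 48 stage list tests against 26, with 3 by fry. Of the 27 named entries, those called with their sign numbered 20 with the processed signal, 19 with the matrix values, 26 without the dye coefficient, 22 with the extraction day as a fixed block, 27 with it as a random block, 27 without a filter and 19 in arrays of 1 source-code prefix. The others kept their sign and lost the call. No setting turned the chloroplast ribosomal protein L2 call of ms23 at 1.5 mm (CHZMRPL2P) or ended it.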

Other observations

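Both the stage-to-stage comparison of effects and the set of tagged probes were examined only after the values had been seen.

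The effects of msca1 recurred from stage to stage. In msca1 599 probes were called at both 1.5 and 2.0 mm, all 599 in the same direction, against 86.0 for independent lists, and 155 at both 1.0 and 1.5 mm, all in the same direction (13.5). ZML32, of unstated product, is among the probes lower at both 1.5 and 2.0 mm. In ms23 447 probes were called at both 1.0 and 1.5 mm, 445 in the same direction (108.7 for independent lists), with ribosomal proteins L39 (ZMRPL39), S21 (ZM40SS21) and tryptophan synthase beta (MZEORP1A) lower at both. In mac1 122 were called at both 1.5 and 2.0 mm, 107 in the same direction (43.7), and 100 at both 1.0 and 1.5 mm, 97 in the same direction (22.1), with ribosomal protein S28 (ZMRPS28) lower at both. Across probes, which are not independent replicates, Pearson's r between the effects at 1.5 and 2.0 mm was 0.74 in msca1, 0.30 in mac1 and 0.27 in ms23. Between 1.0 and 1.5 mm it was 0.66 in msca1, 0.28 in mac1 and 0.61 in ms23. These correlations were not tested against each other. Arrays of 2.0 mm correlated with each other at 0.45 to 0.51 in msca1, 0.30 to 0.38 in mac1 and -0.19 to 0.31 in ms23. For 1.5 mm the ranges were 0.57 to 0.68, 0.65 to 0.79 and 0.23 to 0.47 in that order. Agreement between arrays, signal and extraction days differ between the families, so their part cannot be told apart from that of the mutations. Samples of different stages can share a plant code, and calls at different stages share the spread of each probe in the fit.

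The 224 probes whose accession carries a tag of unstated meaning were tested as a set in 15 comparisons. In msca1 at 2.0 mm 26 of them were lower and 3 higher, so that 12.9% were called against 6.9% of all probes (Fisher's exact test, odds ratio 2.04, adjusted p = 0.018). Limma's camera gave adjusted p = 0.0021 for a shift down, and adjusted p = 0.69 with an estimated correlation. In the msca1 average 35 were lower and 8 higher (19.2% called against 14.4%; Fisher's exact test, adjusted p = 0.22). Camera gave adjusted p = 0.032 for a shift down there, and adjusted p = 0.92 with an estimated correlation.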
